A study of Homo sapiens with 10 samples.

How the data were processed

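RNA was measured in the human colon cancer cell line SW620 and in derivatives of it that had grown out as metastases in balb/c nude mice and were then expanded in culture. Per the labels, 4 arrays hold parental cells, 3 hold liver metastasis derivatives and 3 hold lung metastasis derivatives, all labelled as biological replicates. The labels do not say whether replicates of a derivative are separate metastases or separate cultures of 1 derivative, so the p-values measure the spread between these samples only.

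Total RNA was extracted with an RNeasy mini kit, labelled with biotin and hybridised to an Affymetrix HG1.0ST chip, per the labels' protocols. The deposited values are log2 expression values. They were made with RMA (background correction, quantile normalization and summary of the probes of a feature) and the R package oligo, per the submitters' processing notes, which give no version and no summary level. The values lay between 2.55 and 13.99 and the medians of the 10 arrays between 8.62 and 8.72, so no log was taken. Because RMA places arrays on a common distribution, a change in the total RNA content of the cells cannot be seen in these values. The number of arrays, and for dim rows the signal over background, limits the precision.

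The table analysed here has 65535 rows, which with a header is the row limit of an older spreadsheet format, so it may be incomplete. The summary level is not stated, and with a median of 10 rows per gene the rows were taken as probe sets for parts of genes. The platform annotation lists at least 1 gene for 56949 rows, which were the rows tested; 54806 of them list 1 symbol and 2143 list several, and no gene was named from the latter. The other 8586 rows have no listed gene and are unnamed here. The 54806 rows carry 4727 symbols, of which 4102 match a current symbol in a RefSeq gene table of GRCh38.p14 and 601 were updated through a synonym, while 24 were kept as listed, which gave 4713 genes with 1 to 107 rows each. Of these genes 4660 lie on chromosomes 1, 10, 11 and 12 and 29 elsewhere, so every count below covers those chromosomes, and genes on the others are not analysed here. The genome build of the array annotation is not given in the sources used here, so no coordinates are printed and the gene table served only for names, chromosomes and the order of neighbouring genes.

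Each row was fitted with limma (version 3.58.1, R 4.3.3) with 1 coefficient per group over all 10 arrays, which share 1 estimate of the spread, and with no covariate. The 3 contrasts were tested two-sided with eBayes, and p-values were adjusted by the Benjamini-Hochberg method over the 56949 rows of each contrast. A row was called at an adjusted p under 0.05, with no filter on dim rows. Adjusted p-values of single genes in the text come from limma, from these fits or, where said, from the same fit with the array set as a term or on the mean of all rows of a gene. Changes are differences of mean log2 values, with the standard error (SE) of the moderated fit.

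Named genes followed a rule fixed before the data were examined. For each comparison they are the 12 largest rises and 12 largest falls among called rows with 1 symbol in which every array of one group lay above every array of the other, up to 4 called members of each gene list with the smallest adjusted p, and PTHLH with the p38 kinases MAPK11, MAPK12, MAPK13 and MAPK14. A gene with several rows is represented by its brightest row, and the number of its rows that were called is given for the genes that matter most. Genes named outside this rule are described as chosen after their values were seen. Near-identical paralogs (KLRC1 to KLRC4, the AKR1C family, the SPRR2 and NBPF families) can share probes, so their separate values are uncertain.

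The 27 gene lists were also fixed beforehand and cover epithelial junction and keratin, mesenchymal, intestinal differentiation, intestinal stem cell, Wnt target, TGF-beta response, p38 MAPK pathway, ERK feedback and early response, matrix protease, integrin and adhesion receptor, hypoxia and glycolysis, cell cycle, type I interferon, MHC class I, NF-kB and chemokine, unfolded protein and amino acid stress, cholesterol synthesis, NRF2 and detoxification, p53 target, Notch and cancer-testis antigen genes, mediators of lung colonisation reported in breast cancer, and hepatocyte, lung epithelial, fibroblast and stromal, endothelial and leukocyte genes as markers of other cell types. Lists with at least 3 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 25 lists tested within each comparison; the MHC class I list had 0 measured members and the cancer-testis list 1. The 4 chromosomes were tested in the same way. Permutation p-values of neighbouring genes were adjusted over their 6 tests. Overlap between the liver and lung changes, which share the parental arrays, was set against simulated unchanged groups, against independent lists, and against splits of the parental arrays.

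The scripts were tested on simulated data, with noise drawn independently for each row or gene and with no array set. The results below therefore do not show how the tests behave with correlated genes or an array set. With 56949 simulated rows, the liver against parental fit recovered 83.3% of rows changed 4-fold, 46.3% of rows changed 2-fold and 14.9% of rows changed 1.5-fold, with 9 false calls among 105. For lung against parental cells the shares were 87.9%, 44.8% and 8.96%, with 6 false calls among 100, and for lung against liver derivatives 81.8%, 37.3% and 14.9%, with 6 among 95. In 4713 simulated genes camera called 20 of 20 lists shifted by 0.50 log2 units and 0 unshifted lists. A shuffling test of neighbouring genes, run on 4098 genes, called 20 of 20 simulated sets with shifted stretches and 1 of 20 without.

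Alternatives were quantile normalization, median centring, removal of rows under the 33rd percentile of brightness, all 65535 rows, 1 row per gene, an intensity trend with a robust prior, array weights, only the 2 groups compared, the replicate number as a block, a minimum change of 1 log2 unit, an unequal-variance test per row, and leaving out each array in turn. After seeing the data, 3 more were added: a term for a set of arrays described in the report (parental array 4 with the 3 lung arrays), the mean of all rows of a gene as the unit, and both together.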

Results

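Expression was profiled in parental SW620 colon cancer cells (4 arrays) and in derivatives of this line selected in nude mice for growth in the liver (3 arrays) or the lung (3 arrays). The comparisons ask how each kind of derivative differed from the parental line, how the 2 kinds differed from each other, and which changes they shared. The tested table covers 4713 genes, almost all on chromosomes 1, 10, 11 and 12, in 56949 rows, taken here as probe sets for parts of genes.

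The arrays separated by group along the second principal component and by another split along the first. Parental arrays had scores from -81.3 to -21.0 on component 2 (16.9% of the variance) and derivative arrays from 7.58 to 46.7. On component 1 (38.3%) parental array 4 scored 40.7 and the lung arrays from 66.4 to 98.2, while parental arrays 1 to 3 scored from -63.5 to -47.6 and the liver arrays from -39.1 to -37.3. Pearson correlations across rows, which are not independent replicates, ranged from 0.986 to 0.988 among parental arrays 1 to 3 and from 0.965 to 0.968 between these and parental array 4. Parental array 4 correlated at 0.963 to 0.964 with the lung arrays, against 0.941 to 0.957 for parental arrays 1 to 3. No 2 arrays held the same values. Parental array 4 and the 3 lung arrays are called array set B below and the other 6 arrays array set A. The labels give no batch, and the sets were defined after seeing the data. With the set as a term in the model, the lung derivatives are compared with parental array 4 alone. In the lung comparisons, the value marked set after a log2 change is the change with this term.

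**Figure D1:**
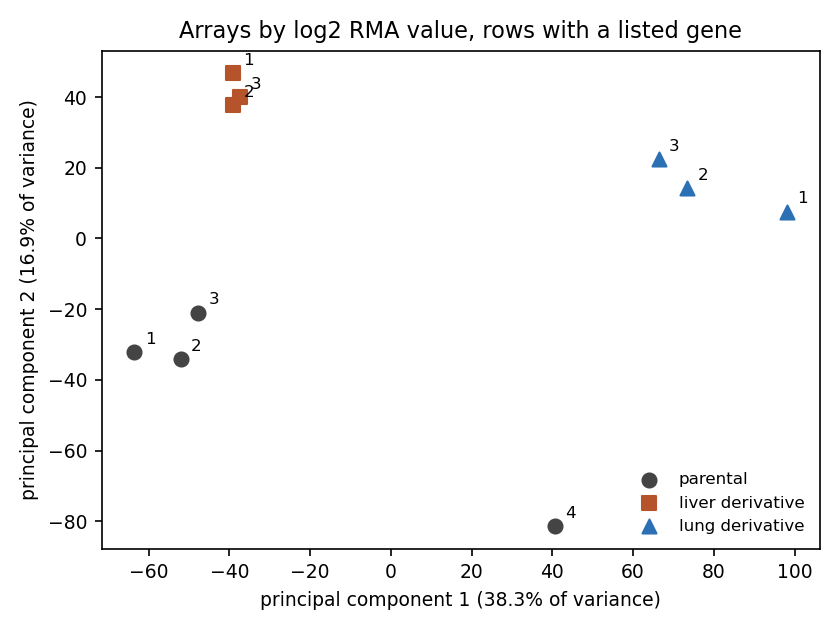
Scores of the 10 arrays on principal components 1 (x axis, 38.3% of the variance) and 2 (y axis, 16.9%) of the log2 values, with a point per array, shape and colour by group, and the replicate number beside it. Parental array 4 lies at 40.7 on component 1, on the side of the lung arrays, and all 4 parental arrays lie below 0 on component 2.

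By the brightest row of each gene, the largest changes in liver derivatives were rises of KRT5, KLRC3 and RAB25 and falls of LUM and CAMK2N1. KRT5, a keratin of basal and squamous epithelium, was 16.6-fold higher than in parental cells (log2 change 4.05, SE 0.22, adjusted p = 4.11e-05; 11.80 ± 0.08 against 7.75 ± 0.41, SD, n = 3 and 4). RAB25, a GTPase of apical recycling endosomes in epithelial cells, was 14.5-fold higher (3.86, SE 0.13), with all 5 of its rows called. ADGRL2, an adhesion G protein-coupled receptor listed on the array as LPHN2, was 5.04-fold higher with 23 of its 26 rows called. The small secreted protein MUCL1 rose in 9 of 10 rows, by 1.85 (SE 0.22) in the brightest and by 3.46 as the mean of its rows, against 3.01 for RAB25 and 2.31 for KRT5 by that mean. The falls were led by LUM, a matrix proteoglycan (-2.82, SE 0.32), and by CAMK2N1, an inhibitor of calcium/calmodulin-dependent kinase II (-2.75, SE 0.26).

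Further rises in liver derivatives included DKK1, a secreted Wnt antagonist (2.24, SE 0.43), FAM171A1 (2.20, SE 0.16), SMCO2 (1.76, SE 0.17) and the ETS transcription factor FLI1 (1.69, SE 0.19). The lectin-like receptor genes KLRC3, KLRC2, KLRC1 and KLRC4, known from natural killer cells, rose by 4.02, 3.80, 3.53 and 2.28. Of each, 1 or 2 rows were called, KLRC4 was not called by the mean of all its rows (0.60, adjusted p = 0.0858), and as near-identical neighbours they cannot be read as separate rises. Further falls were AKR1C3, an aldo-keto reductase of steroid and prostaglandin metabolism (-1.80, SE 0.21, 8 of 8 rows), the tetraspanin TSPAN8 (-1.49), AK3L1 (-1.47) and the synaptic scaffold SHANK2 (-1.44). The group also held the organic anion exporter ABCC2 (-1.42, SE 0.12, 18 of 32 rows), SNORA19 (-1.42), BTBD16 (-1.40), PHYHIPL (-1.39), the glutamate receptor subunit GRIN2B (-1.34, 10 of 15 rows) and SMCO4 (-1.19). In all these genes every liver array lay outside the range of the 4 parental arrays.

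Across all rows 1252 were called in liver derivatives, 657 higher and 595 lower, in 368 genes, and 684 of them changed by at least 1 log2 unit. With the array set as a term, 1464 rows were called, 1094 of them among the 1252. Leaving out a single liver array brought the count to between 527 and 552, and leaving out parental array 2 to 714. Called rows clustered by gene: 44.4% of those in genes with at least 4 rows fell in genes with at least 50% of their rows called the same way, 38 genes higher and 20 lower.

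**Figure D2:**
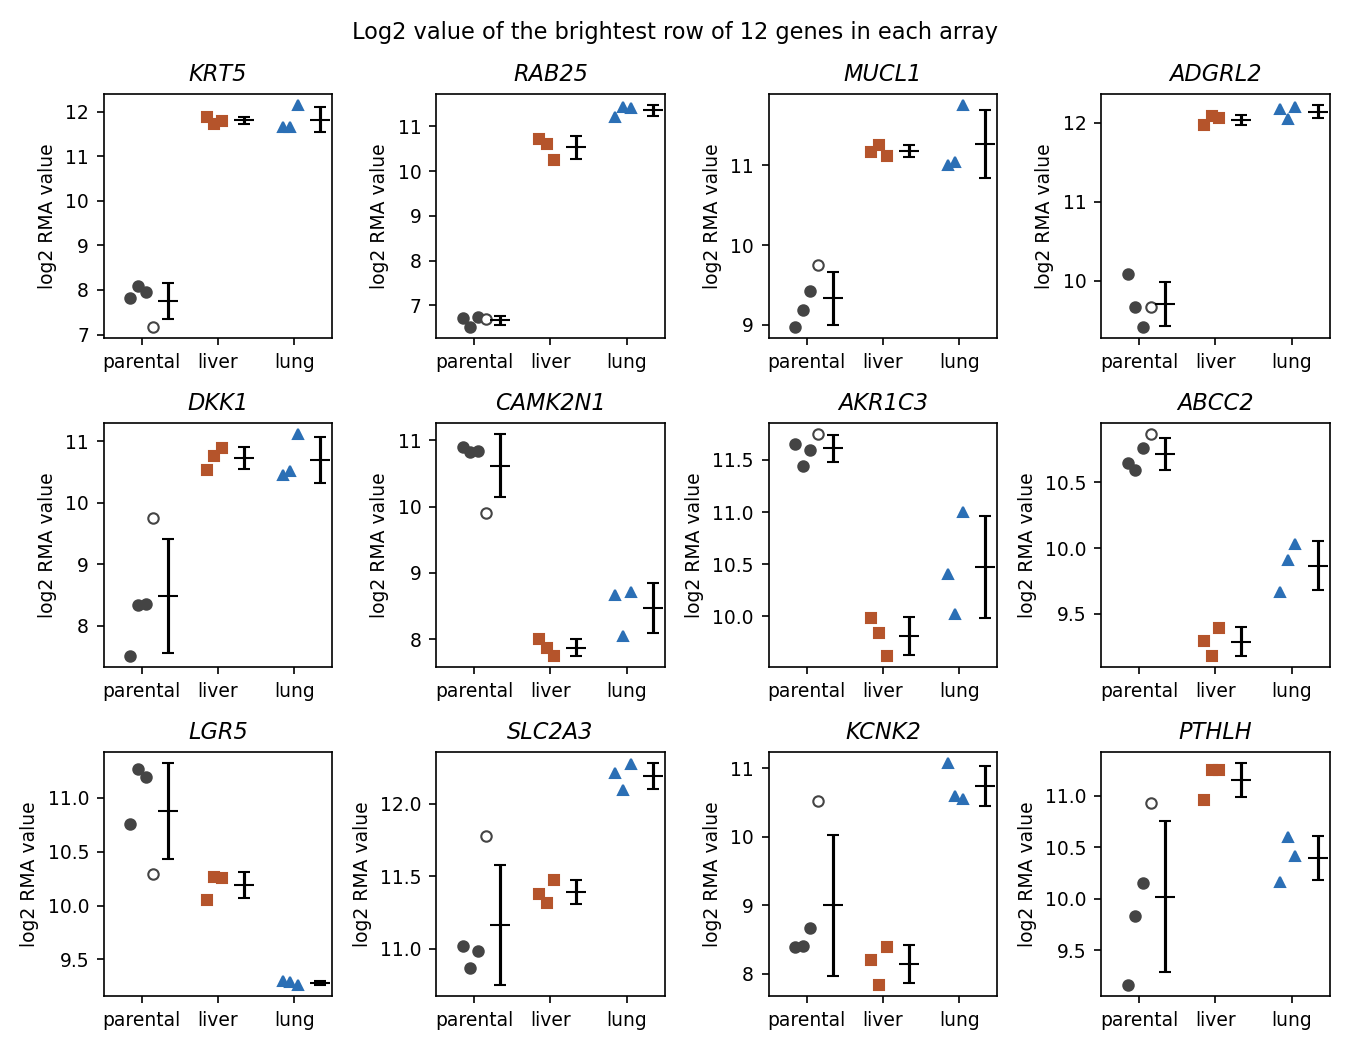
Log2 RMA values (y axes, which differ in range) of the brightest row of 12 genes in each array, by group (x axis). Points are arrays, the open circle is parental array 4, and bars are the mean and SD of the group (n = 4, 3 and 3). KRT5 lies at 7.75 on average in parental cells and at 11.80 and 11.82 in liver and lung derivatives, whereas in KCNK2 parental array 4 lies at 10.52, beside the lung arrays.

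By gene list, with each gene represented by its brightest row, the liver derivatives showed called members in 9 of the 25 lists tested. RAB25 was the called member of 7 measured epithelial genes, and adjusted over the list alone the epithelial transcription factor ELF3 was also lower. In the NRF2 and detoxification list AKR1C3 and ABCC2 fell among 12 (adjusted over the list alone, 2 lower and 1 higher). In the early response list the transcription factor EGR2 was higher (2.82-fold, SE 0.28 log2 units) and JUN lower (-0.82, SE 0.12) among 8, with the same 2 adjusted over the list alone. In EGR2 1 of 4 rows was called, and by the mean of its rows it was not (0.62, adjusted p = 0.0729). LTBP3 was higher (0.46) and the TGF-beta co-receptor TGFBR3 lower (-0.77) among 7 TGF-beta genes, LTBP3 with an adjusted p of 0.0494, and of 0.0519 with the array set as a term. Adjusted over the list alone 2 were higher and 1 lower. Further called members were DKK1 among 7 Wnt targets (adjusted over the list alone, 2 higher and 1 lower), IDI1 (0.53) among 7 cholesterol genes (adjusted over the list alone, 2 higher) and TSPAN8 among 13 adhesion receptors (adjusted over the list alone, 4 lower).

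The intestinal stem cell list was the only list that camera called in liver derivatives, as lower (adjusted p = 0.0462; adjusted p = 0.381 with an estimated correlation). None of its 6 measured members was called over all rows. Adjusted over the list alone 3 were lower: the Wnt-dependent crypt receptor LGR5 (-0.68, SE 0.21), the receptor kinase EPHB2 (-0.40, SE 0.11) and the hyaluronan receptor CD44 (-0.69, SE 0.23). With the array set as a term the adjusted p of the list was 0.132, and the call was lost when any of 5 single arrays was left out. Lists with 0 called members, over all rows and adjusted over the list alone, were mesenchymal (5 measured), intestinal differentiation (5), p38 pathway (9), matrix protease (12), hypoxia and glycolysis (16), cell cycle (6), interferon (15), NF-kB (5), unfolded protein and amino acid stress (8), p53 target (9) and Notch genes (7) and the mediators of lung colonisation (8). In the Notch list the brightest row of NOTCH2 was not called, but 17 of its 33 rows were called higher (mean of all rows 1.15, SE 0.07), a gene chosen after its values were seen. Markers of other cell types gave 0 called of 8 hepatocyte, 6 lung epithelial and 5 endothelial genes. LUM was lower among 7 stromal genes, and the antibacterial enzyme LYZ, also a gut product, was higher (1.44, SE 0.30) among 12 leukocyte genes. The counts, adjusted over the list alone, were the same.

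Lung derivatives carried the same leading rises. RAB25 was 25.8-fold higher than in parental cells (log2 change 4.69, SE 0.13, adjusted p = 1.53e-06; 11.35 ± 0.12 against 6.67 ± 0.11, SD, n = 3 and 4) in 5 of 5 rows, and 4.67 above parental array 4. The fold is again set against a dim parental level. KRT5 was 16.8-fold higher (4.07, SE 0.22; 4.66 against array 4) and ADGRL2 5.41-fold (2.43, SE 0.15; 2.47 against array 4; 24 of 26 rows). TH, the rate-limiting enzyme of catecholamine synthesis, was 4.36-fold higher (2.12, SE 0.14; 2.22 against array 4). CAMK2N1 was lower by 4.42-fold (-2.14, SE 0.26; -1.43 against array 4), and the crypt receptor LGR5 by 3.02-fold (-1.59, SE 0.21; 17 of 18 rows; -1.01 against array 4).

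The KLRC3 (3.75, set 4.02), KLRC2 (3.26, set 2.79), KLRC1 (3.08, set 2.95) and KLRC4 (2.38, set 1.99) rows rose, with the same doubt about shared probes. FAM171A1 (3.99-fold; 2.40 log2 units against array 4), MUCL1 (1.93, set 1.51), DKK1 (2.21, set 0.95) and LYZ (2.03, set 1.15) were also higher. By their brightest rows MUCL1, DKK1 and LYZ were not called against parental array 4, a single array. By the mean of all rows they were 2.45, 0.43 and 1.18 above it. Array 4 alone held the brightest row of DKK1 at 9.74 and that of LYZ at 9.27 against parental means of 8.48 and 8.39. Other falls were SHANK2 (-1.94, set -1.42), SCARNA11 (-1.59, set -0.60), SNORA19 (-1.56, set -0.76), the transcription factor WT1 (-1.56, set -1.20) in 9 of 11 rows, SIK2 (-1.43, set -0.99), SLCO1B3 (-1.38, set -2.46), NCR3LG1 (-1.35, set -1.33), SCARNA9 (-1.29, set -1.01), DENND5B (-1.29, set -0.59) and PRR4 (-1.28, set -0.35). Of these falls SHANK2, SLCO1B3 and NCR3LG1 were also called against parental array 4 by their brightest row. By the mean of all rows WT1, NCR3LG1 and DENND5B changed by -1.12, -1.04 and -0.81 against that single array. PRR4 was not called by the mean of all its rows (-0.08). The brightest row of SLCO1B3 lay at 8.71 in parental array 4 against 7.24 to 7.34 in the other parental arrays. That is away from the lung arrays and enlarges its set value.

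Over all rows 7483 were called in lung derivatives, 2933 higher and 4550 lower, in 2700 genes. With the array set as a term 635 were called, 424 higher and 211 lower, and 397 of these were among the 7483. The share of higher calls was 39.2% as deposited, 49.1% after quantile normalization and 49.4% after median centring. With 1 row per gene, the brightest, it was 70.1% (737 higher and 314 lower), so the balance depends on the rows used. In genes with at least 4 rows, 17.7% of called rows fell in genes with at least 50% of their rows called the same way. The count fell to 2519 without parental array 2 and rose to 16222 without parental array 4.

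In the stem cell list LGR5, EPHB2 (-0.56, set -0.47) and CD44 (-1.17, set -1.35) fell among 6, and the same 3 adjusted over the list alone. Camera gave the list an adjusted p of 0.0893 (adjusted p = 0.575 with an estimated correlation) and, with the array set as a term, 0.000633 (adjusted p = 0.242 with an estimated correlation). In the NRF2 list AKR1C3 (-1.14, set -1.27) and ABCC2 (-0.85, with an adjusted p of 0.0374 with the set term) fell and AKR1C1 (0.67, set 0.30) rose among 12, with the doubt about shared probes in the AKR1C family and AKR1C1 not called by the mean of its rows (adjusted over the list alone, 1 higher and 3 lower). EGR2 (1.76, set 1.55) rose and JUN (-1.08, set -0.82) fell among 8 early response genes, and the same 2 adjusted over the list alone. In the hypoxia and glycolysis list the glycolytic enzyme PGAM1 (0.53, set 0.47), in 4 of 4 rows, and the glucose transporter SLC2A3 (1.03, set 0.42) rose among 16, with the same 2 adjusted over the list alone. Parental array 4 held SLC2A3 at 11.78 against 10.87 to 11.02 in the other parental arrays. The proteases CTSS (1.02, set 0.79) and MMP3 (1.05, set 0.58) rose among 12, also adjusted over the list alone. Of the genes in these lists, ABCC2, JUN and CTSS were also called against parental array 4 by their brightest row. By the mean of all rows the change against that single array was -1.11 in LGR5, -1.24 in CD44 and -1.40 in AKR1C3. It was 0.42 in PGAM1 and 0.50 in SLC2A3.

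Adhesion receptors moved both ways in lung derivatives: among 13, TSPAN8 (-0.86, set -1.09), CD44 and NCAM1 (-0.72, set -0.31) fell, and the integrin subunits ITGA10 (1.16, set 1.08) and ITGA8 (1.17, set 0.26), the latter chosen after its values were seen, rose (adjusted over the list alone, 4 higher and 4 lower). TAGLN (-0.72, set -0.69) fell among 5 mesenchymal genes (adjusted over the list alone, 3 lower). The centromere protein CENPF (-0.53, set -0.18) fell among 6 cell cycle genes and the serine synthesis enzyme PHGDH (-0.35, set -0.39) among 8 stress genes, each the single member adjusted over the list alone. DUSP16 (0.78, set 0.14), a phosphatase of stress-activated kinases, rose and the kinase MAP3K6 (-0.62, set -0.43) fell among 9 p38 pathway genes, with the same 2 adjusted over the list alone. LTBP3 (0.42, set 0.37) and TGFBR3 (-0.38, set -0.45), DKK1 with LGR5, RAB25 and IDI1 (0.46, set 0.39) were the called members of the TGF-beta, Wnt, epithelial and cholesterol lists. These held, adjusted over the list alone, 2 and 1, 3 and 1, 1 and 1, and 1 and 0 members higher and lower. Of 15 interferon genes OAS1 (0.71, set 0.41) and TRIM22 (0.85, set 0.64) rose and IFI6 (-0.59, set -0.29) and IFIT5 (-0.51, set -0.46) fell (adjusted over the list alone, 3 and 2). Higher members were CSF1 (0.42, set 0.31) and BIRC3 (0.95, set 0.29) of 5 NF-kB genes, NOTCH2 (1.21, set 0.09) of 7 Notch genes, and KRT81 (1.09, set 0.46) and ST6GALNAC5 (0.40, set 0.17) of 8 mediators of lung colonisation, where CD44 was lower. The counts, adjusted over the list alone, were the same. Of the genes in this paragraph only TSPAN8 and RAB25 were called against parental array 4 by their brightest row. The mean of all rows changed against that single array by -0.96 in NCAM1, -1.24 in CD44, -1.11 in LGR5 and -0.45 in PHGDH. In CENPF and KRT81 it changed by -0.36 and 0.20. By the mean of all rows of the gene ITGA8 (0.09), ITGA10 (0.20), IDI1 (0.09), TRIM22 (0.09), IFI6 (-0.12), IFIT5 (-0.08), CSF1 (-0.05) and ST6GALNAC5 (0.14) were not called. Of 5 intestinal differentiation genes 0 were called (adjusted over the list alone, 2 higher), and of 9 p53 targets 0 by either count.

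A minority of the markers of other cell types were called in the lung arrays, all as higher: PDPN (0.68, set 0.26), SFTPA1 (0.65, set 0.24) and AQP5 (0.54, set 0.35) of 6 lung epithelial genes (adjusted over the list alone, 5 higher), C1R (0.87, set 0.56) and ACTA2 (0.56, set 0.43) of 7 stromal genes (adjusted over the list alone, 2 higher and 1 lower). Also higher were APOA1 (0.52, set 0.25) of 8 hepatocyte genes (adjusted over the list alone, 2), ROBO4 (0.99, set 0.22) of 5 endothelial genes (2) and LYZ and S100A9 (0.55, set 0.18) of 12 leukocyte genes (5). Brightest rows leaned upward in general: with 1 row per gene tested, 737 genes were called higher and 314 lower. A higher direction by itself is thus not particular to these markers. Camera, which sets a list against the other genes, gave the lung epithelial list an adjusted p of 0.0893. With an estimated correlation its camera adjusted p was 0.575. The median change of that list was 0.49, and 0.26 against parental array 4. The medians of the other marker lists were 0.39 (leukocyte), 0.30 (stromal), 0.07 (endothelial) and -0.05 (hepatocyte). Against parental array 4 none of these marker rows was called, though the mean of all LYZ rows was 1.18 above that single array. By the mean of all rows of the gene AQP5, ACTA2 (0.11), APOA1, ROBO4 and S100A9 were not called. Camera called 0 lists in this comparison (5 at an unadjusted p under 0.05; 13 lists with fry, which tests each list without reference to other genes).

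Between the derivatives, RAB25 was higher in lung than in liver (0.83, SE 0.14, adjusted p = 0.0201; 0.80 with the set term) in 5 of 5 rows. Also higher were PGAM1 (0.54, set 0.45) in 4 of 4 rows, LUM (1.85, set 0.79) in 3 of 6 rows and the protease CTSS (2.01-fold; 0.71 log2 units with the set term). Lower in lung were CENPF (-0.77, set -0.30) in 13 of 21 rows, FLI1 (-1.26, set -0.72) in 5 of 10 rows and LGR5 (-0.91, set -0.13) in 2 of 18 rows. The largest rises by single rows were SPRR2D (2.81, set 0.63), the potassium channel KCNK2 (2.60, set 0.57), LDHC (2.55, set 1.09), RABGAP1L (2.49, set 0.62), TECTB (2.43, set 0.15), ITGA8 (2.27, set 1.07), AQP10 (2.24, set 1.22), ADCY10 (2.24, set 0.68), PHF13 (2.22, set 0.60), PTH (2.21, set 0.80), HEPACAM (2.20, set 0.25) and TNR (2.19, set 0.39). The largest falls were HOXC4 (-1.36, set 0.14), NR2C1 (-1.35, set -1.51), PRR4 (-1.32, set -0.08), ARHGAP29 (-1.30, set -0.55), FLI1, MMEL1 (-1.26, set -0.21), ZNF678 (-1.24, set -0.81), BBS1 (-1.24, set -0.29), NBPF1 (-1.19, set -0.45), GLYATL1 (-1.18, set -0.16), PODN (-1.16, set -0.06) and MASP2 (-1.13, set -0.32).

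These single-row changes mostly stood beside other rows of the gene that were not called: 1 of 11 in LDHC, 2 of 30 in ITGA8 and 3 of 13 in KCNK2, and in RABGAP1L 2 rows were called higher and 6 lower among 37. By the mean of all rows LDHC, RABGAP1L, TECTB, ITGA8, AQP10, ADCY10, PRR4, ARHGAP29, MMEL1, ZNF678, GLYATL1, PODN and MASP2 were not called. Rows called in both directions were also found in AQP10, ADCY10, ARHGAP29, MMEL1, ZNF678 and MASP2. Parental array 4 lay near the lung level in KCNK2 (10.52 against 10.74 in lung and 8.14 in liver), TECTB (11.04 against a liver mean of 8.58) and HOXC4 (8.41 against 8.51 and 9.88).

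Over all rows 7194 differed between the derivatives, 2859 higher and 4335 lower in lung, in 2807 genes. With the array set as a term 36 were called, 28 higher and 8 lower, and 6 of these were among the 7194. None of the genes named for this comparison was called then by its brightest row. The term also widened the standard errors, from 0.08 to 0.13 for the mean of the RAB25 rows. The brightest rows of RAB25, TAGLN, IRF7 and NR2C1 kept about their size, so a lost call is not by itself a lost change. With the mean of all rows of a gene and the set term, 4 genes were called, chosen after their values were seen: RAB25 (1.05, SE 0.13, adjusted p = 0.0209) as higher and the adhesion molecule CNTN1 (-1.21, SE 0.10, adjusted p = 0.00236) as lower, with 0.99 and -1.28 without the set term, and CAMK2N1 (1.04, SE 0.13) and NCAM1 (0.82, SE 0.10). The last 2 rest on the single value of parental array 4. By mean of rows NCAM1 was at 6.69 in lung and 6.87 in liver derivatives, a difference of -0.18 without the term, with 7.65 in parental array 4 and 8.65 in parental arrays 1 to 3. CAMK2N1 differed by 0.29 without the term, with 8.86 in parental array 4 and 9.61 in parental arrays 1 to 3. The higher share was 39.7% as deposited, 51.5% after quantile normalization and 48.8% after median centring. With 1 row per gene, the brightest, it was 64.0% (757 higher and 426 lower). Without liver array 2 or 3 the count was 0, with 14430 and 14800 rows at an unadjusted p under 0.05.

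**Figure D3:**
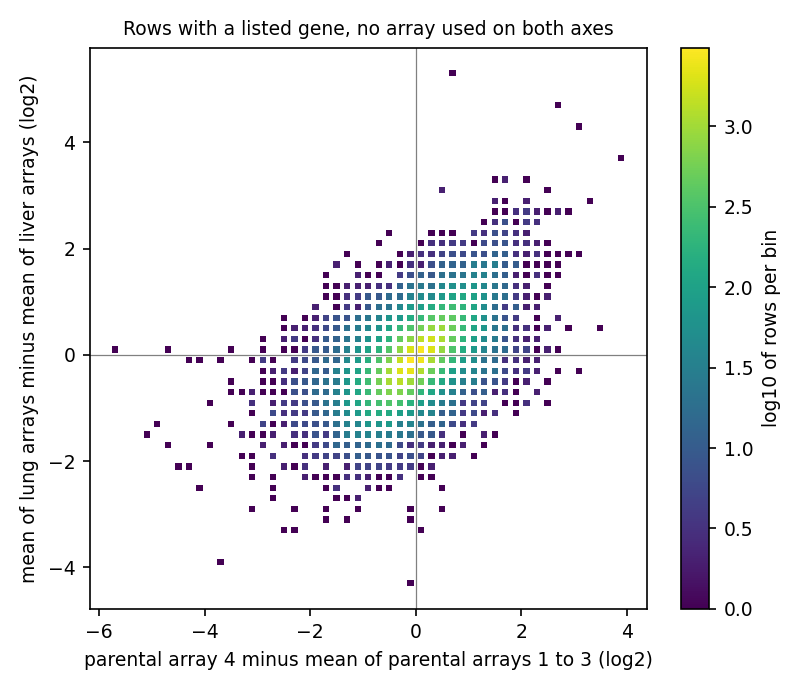
Change from parental arrays 1 to 3 to parental array 4 (x axis, log2) against the change from liver to lung arrays (y axis, log2) over 56949 rows, drawn as bins of 0.2 log2 units coloured by the log10 number of rows. The axes share no array, and the Pearson correlation across rows is 0.580.

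Camera called 0 lists between lung and liver derivatives (4 at an unadjusted p under 0.05; 8 with fry). Members called higher in lung by their brightest row were RAB25 and ELF3 (0.73, set 0.35) of 7 epithelial genes, CTSS, MMP3 (1.02, set 0.40) and ADAM12 (0.73, set -0.01) of 12 proteases, and TSPAN8 (0.63, set 0.33), ITGA8, ITGA10 (0.88, set 0.78) and MCAM (1.05, set 0.05) of 13 adhesion receptors. The same held for PGAM1, SLC2A3 (0.80, set -0.01) and DDIT4 (1.12, set 0.30) of 16 glycolysis genes and OAS1 (0.92, set 0.53) and TRIM22 (0.81, set 0.53) of 15 interferon genes, where IRF7 (-0.55, set -0.56) was lower. The counts of higher members, adjusted over the list alone, were 2, 6, 4, 4 and 2. Over all rows of MCAM 1 was called higher and 1 lower, with a mean of -0.35. By the mean of all rows MMP3, ADAM12, ITGA8, ITGA10, MCAM, SLC2A3, TRIM22 and IRF7 were not called. Also higher were GPA33 (1.64, set 0.19) of 5 intestinal differentiation genes, CSF1 (0.53, set 0.37) and BIRC3 (1.08, set 0.20) of 5 NF-kB genes, NOTCH2 (1.37, set -0.12) of 7 Notch genes, and KRT81 (0.95, set 0.11) and ST6GALNAC5 (0.44, set 0.14) of 8 mediators of lung colonisation. In NOTCH2, however, 10 of 33 rows were called lower and 1 higher, and the mean of its rows was lower (-0.53). Higher members of these lists, adjusted over the list alone, numbered 2, 2, 1 and 2. By the mean of all rows GPA33, CSF1, BIRC3, KRT81 and ST6GALNAC5 were not called. Members called lower were TAGLN (-0.78, set -0.74) of 5 mesenchymal genes, LGR5 in the stem cell and Wnt lists, CENPF, the sterol desaturase SC5D (-0.56, set -0.19), MAP3K6 (-0.67, set -0.42) of 9 p38 pathway genes, and the epoxide hydrolase EPHX1 (-1.07, set -0.10), the last beside ABCC2 (0.58, set 0.38) and AKR1C1 (1.03, set 0.54), which were higher. Adjusted over the list alone 4, 1, 1, 1, 2, 1 and 3 were lower in these lists. In MAP3K6 3 of 32 rows were called higher and 3 lower, and by the mean of all rows MAP3K6 (-0.12), TAGLN (-0.22) and AKR1C1 were not called.

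Markers of all other cell types except hepatocytes had called members that were higher in lung than in liver derivatives: PDPN (0.67, set 0.11) and AQP5 (0.58, set 0.32) of 6 lung epithelial genes, LUM and C1R (0.74, set 0.33) of 7 stromal genes, ESAM (1.04, set 0.07) and ROBO4 (1.18, set 0.15) of 5 endothelial genes, and MS4A1 (1.21, set 0.41) and S100A9 (0.60, set 0.10) of 12 leukocyte genes. Of 8 hepatocyte genes 0 were called. Higher members, adjusted over the list alone, numbered 4, 5, 2, 3 and 2. Brightest rows of all genes leaned the same way, with 757 called higher and 426 lower when 1 row per gene was tested. By the mean of all rows AQP5, C1R, ESAM, ROBO4 and S100A9 were not called.

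Many of the rows that changed in liver derivatives changed the same way in lung derivatives. RAB25, KRT5, ADGRL2, MUCL1 and FAM171A1 rose in both, and CAMK2N1, AKR1C3, ABCC2, SHANK2 and TSPAN8 fell in both. Of the 1252 rows called in liver and the 7483 called in lung derivatives, 831 were called the same way in both, 431 higher and 400 lower, and 5 in opposite ways. Independent lists of these sizes would share 33.8 higher and 47.5 lower rows. The log2 changes correlated at 0.330 across rows, with a covariance of 0.0640, where simulated unchanged groups against the same controls gave 0.429 and 0.0299, a difference in covariance of 0.0341. With the parental arrays split 2 and 2, the shared count was 296 to 404 in the 6 splits, and the correlation was 0.355 to 0.439 where parental array 4 served the lung side and -0.06 to 0.005 where it served the liver side. With liver compared with parental arrays 1 to 3 and lung with parental array 4, so that no control was shared and each comparison stayed in 1 array set, 278 rows were called the same way (180 higher and 98 lower), 3 in opposite ways, and independent lists would share 5.76 and 2.56. The lung side of this comparison has 1 control array, whose own deviation enters every lung change, and the spread comes from the other groups. Of the 1464 rows called in liver derivatives against parental arrays 1 to 3, 94.6% had the same sign between parental array 4 and the lung arrays, with no array in common, against 59.5% of the rows not called.

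PTHLH, which encodes parathyroid hormone-related protein and which work on derivatives of this kind concerns, was 1.14 log2 units above parental cells in liver derivatives (SE 0.34, adjusted p = 0.174) and 0.38 above in lung derivatives (SE 0.34, adjusted p = 0.478). The lung minus liver difference was -0.76 (SE 0.36, adjusted p = 0.177). Parental array 4 held it at 10.93 against a parental mean of 10.02 ± 0.74 (SD, n = 4). It was called in liver derivatives by the mean of all its rows (0.93, adjusted p = 0.0494) and, by its brightest row, with the array set as a term (1.44, SE 0.24, adjusted p = 0.0206). With that term the other differences were -0.54 for lung against parental array 4 and -1.98 for lung against liver (adjusted p = 0.489 and 0.245). The p38 kinases MAPK11, MAPK12, MAPK13 and MAPK14 are not among the genes analysed here. Chromosomes 1, 10, 11 and 12 taken whole showed no shift relative to each other by camera in any comparison (0 of 12 tests at an unadjusted p under 0.05). They hold 4660 of the 4713 genes, so a shift common to them could not be seen. At the preset correlation of 0.01 the test is also insensitive for sets of 691 to 1880 genes. The median gene changed by 0.01 to 0.02 in liver derivatives and by 0.05 to 0.10 in lung derivatives.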

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

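The tests of the array set, of whole-gene changes, of cells in parental array 4, of the shared control arrays and of host cells were chosen after the results were seen.

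Parental array 4 stood apart from parental arrays 1 to 3, with a gap to the nearest of them above Dixon's 95% limit for 4 samples, on principal component 1 (40.7 against -63.5 to -47.6) and in 16 of the named genes. Its log2 values were 9.61 for ADAM12, 10.15 for ESAM, 9.90 for CAMK2N1, 10.31 for DENND5B, 11.33 for DUSP16, 9.87 for HEPACAM, 8.41 for HOXC4, 10.52 for KCNK2, 9.55 for LDHC, 9.38 for MASP2, 8.10 for SCARNA11, 11.78 for SLC2A3, 8.71 for SLCO1B3, 6.65 for SNORA19, 11.04 for TECTB and 10.44 for TNR. For TAGLN parental array 3 was the one apart, at 10.56 against 10.40 to 10.42 in the others. Chance puts about 5% of groups past this limit; 18 of the 108 values tested passed it, and over all 4713 genes 7.77% did, with array 4 the array apart in 79.8% of those.

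Parental array 4 may contain cells of a derivative, or it may share a technical array set with the lung arrays. In the genes with rows at least 2 log2 units higher in liver derivatives than in parental arrays 1 to 3 and higher in lung, its level needs a median share of lung derivative cells of 1.61% (38 genes, 95% bootstrap interval -0.764 to 5.64), and with rows at least 1 log2 unit higher 6.23% (103 genes, 0.434 to 15.4). Genes that fell need 38.6% (23 genes, -3.10 to 54.5) and 35.5% (84 genes, 19.2 to 42.8). These shares were computed on the linear scale. On the log2 scale array 4 lay a median 69.7% of the way from parental arrays 1 to 3 to the lung arrays. That median is not a share of cells. It is over 3767 genes, by their rows called in lung but not in liver derivatives against parental arrays 1 to 3. These 3 arrays served to choose the rows and also enter the value, so it can overstate the likeness to lung. Over all rows tested array 4 correlated at 0.963 to 0.964 with the lung arrays and at 0.965 to 0.968 with parental arrays 1 to 3. A mixture has a single share. At 1 log2 unit the interval of the rises (0.434 to 15.4) lies below that of the falls (19.2 to 42.8). This argues against a mixture as the whole cause. At 2 log2 units the intervals overlap, so comparing them does not decide. The interval of the rises at that cut ends at 5.64%, under the 10% set as the limit for this test. A share below that is not excluded. All intervals are over genes in 1 array, so they do not cover the spread between arrays. In the rows without a listed gene array 4 correlated with each lung array by at least 0.00201 more than any of parental arrays 1 to 3 did, which an array set, derivative cells and a separately grown parental culture all predict, so it does not tell them apart, and the labels give neither batch nor passage.

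The lung arrays differed from the liver arrays in 7194 rows, and the same array set is a candidate explanation for most of them. The change from parental arrays 1 to 3 to array 4 correlated with the change from liver to lung arrays at 0.580 across rows, and at 0.632 across rows without a listed gene, although they share no array. Of the rows called between lung and liver 89.4% had the same sign in array 4. Regulation of whole genes stays open. Of these rows 3.69% fell in genes with at least 50% of their rows called the same way, if rows are parts of genes. In liver derivatives the share was 44.4%. Yet by the mean of all rows 937 of 4713 genes were called, against 369 in liver derivatives. A difference between the array sets enters these means too, so that count does not tell regulation from the array set. Lower overall signal of the lung arrays goes with the excess of lower calls: quantile normalization moved 2859 higher and 4335 lower to 3467 and 3260. It left 6727 rows called, so a difference in the overall distribution of values is not needed for most of the count. The deposited values were already quantile normalized, so a large fall in the count was unlikely from the start. A true difference beneath the set rests on parental array 4 alone.

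Liver and lung derivatives shared a change from parental cells. The shared control arrays are argued against as its source by 278 rows called the same way with separate controls, where independent lists give 8.32, although the lung side then has 1 control array and its spread comes from the other groups. Host cells in the cultures stay open: the median of 8 hepatocyte genes in liver derivatives was 0.10 and that of 6 lung epithelial genes in lung derivatives 0.26 (SD over genes at most 0.10, set term), but the hosts were mice and the rise their cells would give on human probes is not known. Selection in the animal and passage history stay open as biological explanations, which these groups cannot separate.

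For liver against parental cells the real grouping of the 7 arrays called 1252 rows, the most of 35 splits, and the highest other split called 82. This argues against random labels on 7 independent arrays, at the smallest share that 35 splits can give. The labels do not say whether the liver arrays are separate metastases or cultures of 1 derivative. A chance difference between cultures is therefore not excluded. For lung against parental cells 2 of 35 splits called as many as the real 7483; the other one set parental arrays 1 to 3 against parental array 4 and the lung arrays and called 13738, which points to the array set, and chance is not excluded. For lung against liver derivatives the 10 splits are too few for a share under 0.05; the real split was 1 of 10, with 7194 rows, and the highest other called 0.

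Among the 8586 rows without a listed gene, which no comparison uses, 43 were called for liver against parental cells, 875 for lung against parental cells and 1066 for lung against liver; with the array set as a term these were 60, 33 and 3.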

How the results depend on the processing

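The 3 alternatives with an array set or with the mean of all rows of a gene were chosen after seeing the data; the others were set before the data were examined. Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated from -0.12 to 0.04. With the number as a replicate block 786, 12420 and 10045 rows were called for liver against parental, lung against parental and lung against liver, in that order, which is used for all triples here, and 0 lists.

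Quantile normalization, median centring, removal of dim rows, all rows of the table and the trend with a robust prior kept all 3 counts within 1.5 times (1234 to 1694, 6918 to 9937 and 6727 to 10657). Other settings moved them: 1 row per gene, which tests fewer rows, 134, 1051 and 1183; array weights 4292, 12778 and 13873; a minimum change of 1 log2 unit 684, 2157 and 2170; the unequal-variance test 223, 21 and 325; and only the 2 groups compared 2120 for lung against parental. The array set as a term gave 635 and 36 rows for the lung comparisons, the mean of all rows of a gene 369, 1420 and 937 genes, and both together 422, 271 and 4. The cause was not tested except for the array set, described above. Leaving out each array in turn gave 527 to 1464, 2519 to 16222 and 0 to 14167 rows.

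The shared count of 831 rows became 821 with quantile normalization, 912 without dim rows, 278 with the set term, 400 to 1123 leaving out each array, and 307, 296, 345, 321, 373 and 404 in the 6 splits of the parental arrays.

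The list call in liver derivatives was lost (0 lists) with an estimated correlation, the gene mean, dim rows left out, the replicate block or the set term; fry called 5, 13 and 8 lists; the gene mean called 2 lists between lung and liver (proteases higher and cell cycle genes lower, adjusted p = 0.0449 each, and adjusted p = 0.512 each with an estimated correlation); and the set term called 1 in lung against parental cells (stem cell genes, adjusted p = 0.000633, and adjusted p = 0.242 with an estimated correlation). Leaving out each array gave 0 to 2 lists in liver derivatives, 0 in lung against parental cells and 0 to 1 between lung and liver. The chromosome tests called 0 under every alternative run.

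The direction of some called genes reversed, all in the lung comparisons, and the cause was not tested. For lung against parental, with the mean of all rows: CSF1 -0.051, AKR1C1 -0.0673, APOA1 -0.0752 and ROBO4 -0.0838. For lung against parental, with that mean and the set term: ITGA10 -0.0131, TRIM22 -0.053, IFI6 0.16, CSF1 -0.14, AKR1C1 -0.26, ST6GALNAC5 -0.0293, APOA1 -0.13, AQP5 -0.0217 and S100A9 -0.0247. For lung against liver, with the mean of all rows: RABGAP1L -0.0505, ARHGAP29 0.30, MMEL1 0.0199, ADAM12 -0.0156, MCAM -0.35, CSF1 -0.0245, NOTCH2 -0.53 and ROBO4 -0.16. For lung against liver, with that mean and the set term: LDHC -0.15, RABGAP1L -0.14, TECTB -0.0449, ITGA8 -0.17, HOXC4 0.14, MMEL1 0.12, GLYATL1 0.19, MASP2 0.0602, ADAM12 -0.0975, ITGA10 -0.0152, SLC2A3 -0.48, TRIM22 -0.13, CSF1 -0.15, BIRC3 -0.0314, AKR1C1 -0.19, NOTCH2 -0.52, KRT81 -0.28, ST6GALNAC5 -0.13, AQP5 -0.12 and S100A9 -0.21. For lung against liver, with the set term alone: HOXC4 0.14, ADAM12 -0.00636, SLC2A3 -0.0134 and NOTCH2 -0.12. PTHLH, not called, went from 0.38 to -0.54 in lung against parental with the set term.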

Other observations

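Further biology lay in genes whose rows changed together, chosen after their values were seen as those with at least 50% of 4 or more rows called the same way (58 genes in liver and 151 in lung derivatives; 43 in both in the same direction, 28 higher and 15 lower). With the array set as a term such genes numbered 71 in liver and 9 in lung derivatives, so the lung values below are followed by the change against parental array 4, marked set. As means of all rows of a gene, the cyclin CCND2 was higher by 2.23 in liver (SE 0.23) and 1.33 in lung (SE 0.23, set 1.93), the retinoid genes CRABP2 by 1.42 in liver (SE 0.11, 10 of 10 rows) and DHRS3 by 0.99 and 1.48 in liver and lung (set 1.37), the carbonic anhydrases CA14 by 1.49 and 1.48 (set 1.43) and CA6 by 1.39 and 1.52 (set 1.44), CD5 by 1.70 in both (set 1.71), and KITLG, the ligand of the KIT receptor, by 1.27 in liver (SE 0.12). The neural protein NELL2 was higher by 1.97 in liver (SE 0.20). All adjusted p-values of these genes were under 0.05 in limma fits of the gene means.

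Genes that fell as a whole included coagulation factor F5 (-1.69 in liver and -1.11 in lung, set -0.97), the cholesterol transfer protein GRAMD1B (-1.56 and -1.48, set -1.54), the adhesion molecule NCAM1 (-1.53 and -1.71, set -0.96), the second aldo-keto reductase AKR1C4 (-1.51 and -1.32, set -0.98), the receptor ROR1 (-1.42 in lung, SE 0.07, set -1.44) and the neuropilin NRP1 (-1.30 in liver, SE 0.18). In lung derivatives the calcium channel ITPR2 fell in 56 of 59 rows (-1.19, SE 0.10), and changed by -1.04 against parental array 4 (SE 0.14).

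A stretch of neighbouring genes on chromosome 10 was higher in both derivatives, and its test was chosen after the data were seen. Over 802 overlapping windows of 25 genes in RefSeq order (neighbours of 1 gene family left out), the window from TASOR2 to CAMK1D had the largest shared shift, with a median change of 0.25 in liver and 0.22 in lung derivatives against the parental arrays of the same array set, 23 and 22 of its 25 genes higher. Of its genes TAF3 (0.41 and 0.39), FBH1 (0.37 and 0.39) and PROSER2 (0.34 and 0.60) were called as higher in both by gene mean, while GATA3 (0.02 and -0.12) was not higher. Per array the median difference from parental arrays 1 to 3 was 0.19 to 0.27 in the liver arrays, 0.11 to 0.18 in the lung arrays and -0.06 in parental array 4. The lung value of the window thus rests on parental array 4 alone, and against parental arrays 1 to 3 each lung array had 17 of the 25 genes higher. No shuffled gene order gave a shared shift as large (permutation p = 0.001, the smallest that 1000 orders can give; highest shuffled value 0.19). Taken alone, the largest lung shift stood less clear of the shuffled orders than the largest liver shift. Shuffling assumes that neighbouring genes change independently, yet 2 arrays of the same group gave correlations of adjacent genes up to 0.180. The permutation p therefore does not separate a gain from array effects on neighbours. A gain of this part of chromosome 10 in the cells that grew out in both organs is a candidate explanation that was not tested, and no DNA measurement bears on it here.

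Whether copy number changes account for the shared change more widely remained undecided. Changes of adjacent genes correlated at 0.146 in liver and 0.126 in lung derivatives (Spearman's rho across 4098 genes, which are not independent replicates; permutation p = 0.001 in each, adjusted 0.002 over 6 tests), but differences between 2 arrays of the same group gave 0.0117 to 0.180, so the order of genes alone cannot separate copy number from array effects.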
